A study of Mus musculus with 10 samples.

How the data were processed

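Poly(A)-selected RNA from the livers of 10 male C57BL/6JRj mice, an inbred laboratory strain, was sequenced as single-end reads of 100 nt from a strand-specific library kit, per the labels' protocols. The mice were 16 weeks old when exposure began. According to the same text, 5 of them spent 16 weeks in cages where, for 8 h a day during their resting phase, the air alternated in cycles of 60 s between 30 s with an oxygen plateau of 5% and 30 s at 21% (intermittent hypoxia), and 5 received air-to-air cycles (normoxia). Each mouse gave 1 library, so replicates are separate animals. Mice 31 to 35 formed the normoxia group and mice 36 to 40 the hypoxia group, so the numbers give no pairing. Exposure cannot be told apart from anything that followed the order of the numbers. The labels give no batch and no time or feeding state at which each liver was taken.

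The authors deposited a table of gene counts per library, with whole numbers that were not normalized. Per the submitters' processing notes, reads were aligned with STAR 2.7.1a and counted with HTSeq on mm10; the gene annotation is not given in the sources used here. Each table lists 24421 gene symbols, in identical order, plus rows for reads outside genes, reads in overlapping genes and reads with more than one alignment. Those rows were kept out of library sizes and tests. Of all rows' total, reads outside genes made up 16.3% ± 0.464 in hypoxia and 16.5% ± 0.61 in normoxia (SD, n = 5 each), multiply aligned reads 13.1% ± 0.674 and 15.02% ± 1.67, and reads in overlapping genes 0.384% ± 0.0254 and 0.452% ± 0.0942. HTSeq leaves multiply aligned reads uncounted, so genes with near-identical copies, such as Hspa1a and Hspa1b or the Saa genes, are undercounted and their values are uncertain.

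The counts in genes ranged from 23604283 to 48946272 per library, and 3 counts correspond to 0.0613 to 0.127 CPM, the count scaled to a common library total. This sets the floor of detection and covers counting error alone. Agreement between libraries was high (Spearman correlation across genes from 0.98 to 0.994), and no pair agreed within sampling noise, as the smallest chi-square per gene between a pair of libraries was 21.9.

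Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by edgeR's filter on group size with its defaults (a minimum count of 10 and a total of 15), which left 12847 genes holding nearly all gene counts. Library composition was scaled by the trimmed mean of M-values (TMM), and the quasi-likelihood F test with robust dispersion compared intermittent hypoxia with normoxia, two-sided, with no covariate. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Fold changes are hypoxia over normoxia on a log2 scale, with a standard error taken as the absolute log2 fold change divided by the square root of F. Printed CPM are scaled by TMM.

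Before the data were examined, 40 gene lists were fixed: 25 of pathways and 15 of cell type markers. Each was tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the 40 lists. It was tested again with an estimated correlation, with fry, and as the mean log2 CPM of its members per mouse in an exact permutation test over all 252 assignments of the mice, two-sided, for which 0.00794 is the smallest possible p. The same exact test was used for measures of library composition. The genes named are the 12 largest increases and the 12 largest decreases among calls that reached a mean of 1 CPM in a group (predicted and clone names left out), up to 4 members of smallest p in each list described, and 15 fixed readouts. Genes outside that rule are said to have been chosen after their values were seen. Coordinates are those of RefSeq for GRCm38, the assembly also called mm10. Of the listed symbols, 23204 matched by current symbol, 1096 by synonym and 121 not at all.

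The functions were tested on simulated counts drawn from these libraries' means and sizes, with 200 of the tested genes changed. At a fold of 1.5, edgeR called 55.2% of the 67 changed genes, at a fold of 2 it called 89.6% of 67, and at a fold of 4 it called 100% of 65, among 12749 genes in that step. Unchanged genes made up 5.26% of the calls. The simulated genes varied independently, with a dispersion set by their mean level alone and no deviating mouse. These rates therefore need not hold for the real libraries. The alternatives were other scalings (DESeq2 size factors, upper quartile, library size alone, TMM without the 20 most abundant genes), DESeq2 1.42.0, voom with quality weights, 1 surrogate variable (sva 3.50.0), edgeR without robust estimation, other filters and thresholds, and each mouse left out in turn. Corrections for transcript GC content and length, and a clock-phase covariate, were added after seeing the data.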

Results

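Liver transcripts were counted in 10 mice, 5 exposed to intermittent hypoxia and 5 kept in normoxia. The comparison asks how the liver transcriptome differs after 16 weeks of repeated oxygen drops, a model of sleep apnea, and the study's title names inflammatory pathways and steatohepatitis as its subject. Libraries held 27644550 to 38802273 gene counts in hypoxia and 23604283 to 48946272 in normoxia. Of 7 measures of depth and composition, none differed past an adjusted threshold of 0.05 by exact permutation test. After adjustment over 7 measures, 1 measure alone could not pass even at the smallest possible p of 0.00794, so this result does not show that the libraries were alike. The closest were the share of counts in the 100 most abundant genes, 44.9% ± 1.15 against 43.3% ± 0.539, and the share of multiply aligned reads (exact p = 0.0397 and 0.0476; adjusted p = 0.148 for both). Without hypoxia mouse 5, the shares of the 10 and of the 100 most abundant genes both passed (adjusted p = 0.0278, exact permutation).

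The chaperone genes Hspa1a and Hspa1b, the clock gene Per2 and the lipid genes Plin5, Agpat2 and Mogat1 were lower in intermittent hypoxia, and the fibrinogen genes Fga and Fgb, Il1a (interleukin-1 alpha) and the sterol carrier gene Stard4 were higher. Hspa1b, a heat-inducible chaperone, averaged 4.87 ± 2.06 CPM in hypoxia and 29.9 ± 16.1 CPM in normoxia (SD, n = 5 each), a log2 fold change of -2.62 ± 0.47 (SE). Per2, a repressor in the circadian clock, averaged 12.4 ± 2.82 against 25.05 ± 5.52 CPM. Plin5, which coats lipid droplets, averaged 38.4 ± 3.76 against 67.8 ± 10.6 CPM, and Agpat2, an enzyme of glycerolipid synthesis, 142 ± 9.57 against 199.8 ± 10.7 CPM. Il1a averaged 4.21 ± 0.677 against 2.36 ± 0.283 CPM, and Fgb, the fibrinogen beta chain, 5745 ± 233 against 4134 ± 555 CPM. In edgeR's quasi-likelihood test 89 of 12847 genes passed, 40 higher and 49 lower, and 13 of them differed by at least 1 on the log2 scale.

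**Figure D1:**
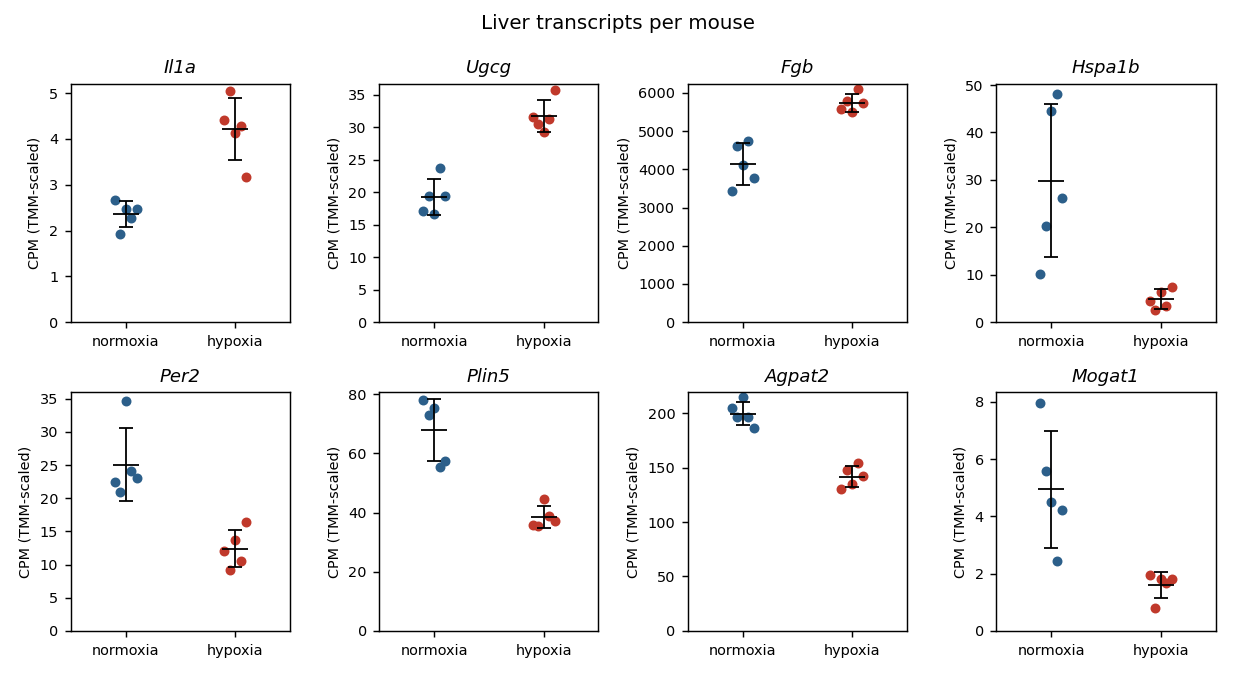
CPM scaled by TMM (vertical axes, linear from 0) of 8 called genes in each mouse, with normoxia in blue and hypoxia in red; points are mice, and black marks give the mean and SD (n = 5). The groups do not overlap in any panel, and Hspa1b spans 10.2 to 48.0 CPM in normoxia and 2.59 to 7.51 CPM in hypoxia.

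Among the other large increases were Srrm4, a neuronal splicing regulator (log2 fold change 1.46 ± 0.23, SE), Bmf, a pro-apoptotic member of the Bcl-2 family (1.34 ± 0.25), Rgs1, a regulator of G-protein signalling in leukocytes (1.25 ± 0.26), and Dlgap1 (1.07 ± 0.21). Ugcg, which makes glucosylceramide, rose by 0.72 ± 0.10 and the kinase Tec by 0.64 ± 0.13 on that scale. Ncald, Abca8a, BC089597, Zfp113 and Mug2 completed the increases, at 0.77, 0.67, 0.66, 0.66 and 0.64. The largest decreases after the Hspa1 pair were Mogat1, an enzyme of triglyceride synthesis (-1.64 ± 0.31), Treh, which splits trehalose (-1.51 ± 0.30), Aatk (-1.41 ± 0.18), Olig1 (-1.22 ± 0.16) and Sema5b (-1.19 ± 0.21). Phospho1, Spc24 and Slc16a13 followed at -0.99, -0.95 and -0.91, and Chchd6 averaged 1.08 ± 0.119 against 2.15 ± 0.510 CPM. Many of these are scarce transcripts: Srrm4 reached 5.85 ± 1.21 CPM in hypoxia, Rgs1 1.72 ± 0.271 CPM and Treh 0.773 ± 0.169 CPM. Ugcg lies on chromosome 4 (59189507 to 59222833), Agpat2 on chromosome 2 (26593057 to 26604417), Plin5 on chromosome 17 (56111597 to 56117606), Per2 on chromosome 1 (91415977 to 91459351) and Hspa1b on chromosome 17 (34956429 to 34959238).

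The 2 groups did not overlap in 87 of the 89 called genes. Over all genes tested, 580 (4.51%) did not overlap, where chance gives 0.794%. The first principal component held 24.1% of the variance and separated the groups (exact permutation p = 0.00794, the smallest the design allows). The number of calls depended strongly on single mice: it was 236, 12, 18, 23 and 204 without hypoxia mouse 1, 2, 3, 4 and 5, and 49, 25, 32, 66 and 52 without normoxia mouse 1, 2, 3, 4 and 5. All 89 genes kept their direction in each of those fits, 27 of the 32 called genes named by rule missed the threshold in at least 1 of them, and with library size alone as the scaling the calls were 17 higher and 52 lower.

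Heat-shock genes were lower as a group. All 16 members lay below normoxia, with a median log2 fold change of -0.56; Hspa1a and Hspa1b passed over all genes and 13 passed adjusted over the list alone. Bag3, a partner of the Hsp70 chaperones, averaged 27.3 ± 6.35 against 56.6 ± 20.2 CPM and Dnaja1 128 ± 29.5 against 211 ± 38.8 CPM (SD, n = 5 each). In camera the list was called lower with the preset correlation (adjusted p = 7.98e-09), and it was not with an estimated one (adjusted p = 0.37). Hspa1a and Hspa1b lie side by side and are near-identical, so their separate values are uncertain. Neither passed without hypoxia mouse 2, 3 or 4 or normoxia mouse 2 or 4, Hspa1b also failed without hypoxia mouse 1 or normoxia mouse 3 or 5 (edgeR adjusted p up to 0.111 for Hspa1b and 0.101 for Hspa1a), and the median of the list stayed between -0.66 and -0.44 whichever mouse was left out.

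Of 20 circadian clock genes, only Per2 passed over all genes (edgeR adjusted p = 0.0257, and 0.0742, 0.0799 and 0.0657 without hypoxia mouse 2, 3 and 4), and Per2 and Rorc, a nuclear receptor that drives clock genes, passed adjusted over the list alone. The list as a whole was not called (camera adjusted p = 0.166), with 8 members above and 12 below normoxia. Clock genes that move in opposite directions offset each other in this test, so it cannot decide whether clock phase differed. Rorc averaged 44.8 ± 9.30 against 70.7 ± 13.4 CPM and Nr1d2 44.5 ± 17.7 against 24.8 ± 7.02 CPM (SD, n = 5 each). The fixed readouts Arntl, Dbp and Per1 did not pass (edgeR adjusted p = 0.515, 0.609 and 0.987), and Dbp was 6.70 CPM in hypoxia mouse 5. A clock-phase score, chosen after the data were seen, averaged -0.999 ± 1.03 in hypoxia and -1.89 ± 0.395 in normoxia (SD, n = 5 each; exact permutation p = 0.0476, and 0.0873 without hypoxia mouse 5).

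Lists of inflammation and liver-secreted proteins lay higher. All 25 measured genes of the NF-kB and cytokine list lay above normoxia. Il1a passed over all genes and 9 passed adjusted over the list alone. The score of this list (mean log2 CPM) was 3.10 in hypoxia mouse 5, 2.28 to 2.47 in the other hypoxia mice and 1.90 to 2.25 in normoxia. Several leukocyte marker lists also lay higher, and whether the cytokine list moved with them was not tested. Tlr2, a receptor for bacterial lipoproteins, averaged 3.09 ± 1.47 against 1.48 ± 0.476 CPM (SD, n = 5 each), Cxcl16 7.63 ± 0.50 against 5.70 ± 1.14 CPM and Tnfaip3, an inhibitor of NF-kB, 2.89 ± 1.04 against 1.68 ± 0.457 CPM. Of 26 acute-phase genes 24 lay above normoxia. Fgb and Fga passed over all genes and 6 passed adjusted over the list alone. Much of this list's rise came from hypoxia mouse 5, with a score (mean log2 CPM) of 8.04. The other hypoxia mice scored 6.94 to 7.08 and the normoxia mice 6.82 to 7.01. Of 29 complement and coagulation genes 27 lay above normoxia and 3 (Kng1, Cfi and C3) passed adjusted over the list alone. Camera called all 3 lists higher (adjusted p = 6.48e-06, 8.22e-05 and 6.21e-06), and with an estimated correlation it called none of them (adjusted p = 0.37 for each). The fixed readouts Saa1, an acute-phase protein, and Ccl2, a monocyte attractant, did not pass (edgeR adjusted p = 0.434 and 0.515): Saa1 was 228.5 CPM in hypoxia mouse 5 and between 16.6 and 29.5 CPM in the other libraries, and without that mouse its log2 fold change was -0.28. Tnf, at 4 to 24 counts a library, and Epo, with 0 counts in every library, were not tested. The count of 0 allows up to 0.127 CPM for Epo in the shallowest library.

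Immediate early genes, which respond within minutes to stimuli, were called higher as a list with the preset correlation and not with an estimated one (camera adjusted p = 0.000264 and 0.37), with Nr4a1, Egr1 and Atf3 past the threshold adjusted over the list alone and none over all genes. Nr4a1 averaged 7.04 ± 4.34 against 1.43 ± 0.702 CPM and Egr1 12.4 ± 6.07 against 4.53 ± 1.76 CPM (SD, n = 5 each). MHC antigen presentation genes were called higher with 14 of 17 members above normoxia (adjusted p = 0.00746, and 0.555 with an estimated correlation), and Nlrc5 was the 1 member that passed adjusted over the list alone. Hypoxia mouse 5 had an MHC score of 5.77, where the other 4 hypoxia mice averaged 4.79.

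Fatty acid oxidation and nuclear respiratory chain genes lay lower. In the list of fatty acid oxidation and PPAR-alpha targets, 25 of 33 members lay below normoxia. Plin5, Acaa1b, a peroxisomal thiolase, and Pex11a, a peroxisome membrane protein, passed over all genes, and 7 lower and 1 higher passed adjusted over the list alone. Acaa1b averaged 1021 ± 58.4 against 1406 ± 172 CPM, and Cpt1a, the rate-limiting carnitine transferase, 303.9 ± 49.0 against 295 ± 34.6 CPM (SD, n = 5 each; edgeR adjusted p = 0.879). Of 28 nuclear respiratory chain genes 26 lay below normoxia and 10 passed adjusted over the list alone, with Cycs, cytochrome c, at 73.6 ± 9.38 against 93.7 ± 8.22 CPM. Camera called both lists lower (adjusted p = 0.000264 and 6.48e-06), and with an estimated correlation neither was called (adjusted p = 0.555 and 0.37). Scores per mouse of the fatty acid oxidation list overlapped, at 7.47 to 7.79 in hypoxia and 7.50 to 8.13 in normoxia (exact permutation p = 0.183). Those of the respiratory chain list did not, at 6.84 to 7.12 and 7.13 to 7.20 (exact permutation p = 0.00794, adjusted p = 0.0794). In fry, which asks whether a list's genes move on balance one way, the respiratory chain, complement and coagulation, and B and plasma cell lists passed (adjusted p = 0.0445 for each). Fry's test for change in either direction, which does not set a list against other genes, called 17 of 40 lists. Among them were triglyceride synthesis, iron and gluconeogenesis genes (fry adjusted p = 0.00184, 0.00321 and 0.0234), which camera did not call. Of all tested genes, 18.9% had an unadjusted p under 0.05 (edgeR), so a list can pass this test without standing out from other genes.

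The steatohepatitis list, whose name is that of a fatty and inflamed liver, was not called by camera (adjusted p = 0.195). It passed fry's test for change in either direction (adjusted p = 0.00338), as did 17 of the 40 lists, this one included. Mogat1 passed over all genes, and Mogat1, Cidec, Cidea, Plin4 and Cd36 passed adjusted over the list alone, each lower. Cd36, and Srebf1 below, lie outside the naming rule and were chosen after their values were seen. Cidec, which enlarges lipid droplets, averaged 2.35 ± 0.709 against 16.0 ± 14.97 CPM (SD, n = 5 each; edgeR adjusted p = 0.0581), and normoxia mouse 1 held 42.8 CPM. In the list of fatty acid and triglyceride synthesis genes (camera adjusted p = 0.221), Agpat2 passed over all genes, and Agpat2, Thrsp, Gck, Pklr and Srebf1 passed adjusted over the list alone, again lower. Scd1, a desaturase, did not pass (28558 ± 3851 against 27210 ± 5680 CPM; edgeR adjusted p = 0.822). Cholesterol synthesis and uptake genes were called higher, with 21 of 25 above normoxia (camera adjusted p = 8.22e-05, and 0.542 with an estimated correlation). The normoxia mice were split on this list. Mice 1 and 5 scored 7.41 and 7.36, level with hypoxia (7.28 to 7.40), and mice 2, 3 and 4 scored 6.86 to 6.97 (exact permutation p = 0.127 between the groups). Stard4, a sterol carrier, rose to 147 ± 20.3 from 97.4 ± 16.3 CPM (edgeR adjusted p = 0.0496), and Hmgcr did not pass (adjusted p = 0.18).

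Several lists of non-hepatocyte markers lay higher, and others were not called. Of 14 sinusoidal endothelial markers all lay above normoxia and 11 passed adjusted over the list alone, none over all genes; Kdr, a VEGF receptor, averaged 35.7 ± 4.93 against 24.5 ± 3.79 CPM (SD, n = 5 each). Of 10 measured B and plasma cell markers 8 lay above normoxia and 6 passed adjusted over the list alone, with Cd19 at 1.19 ± 0.281 against 0.529 ± 0.220 CPM. Camera called both lists higher (adjusted p = 9.77e-07 and 0.000107), and with an estimated correlation neither was (adjusted p = 0.37 for both). With only genes of at least 1 CPM in 5 libraries, 2 of the 10 B and plasma cell markers remained, their median log2 fold change was 0.17 (0.71 without that filter) and the list was not called (adjusted p = 0.487). T and NK cell, Kupffer cell, monocyte, neutrophil and stellate cell markers were also called higher (camera adjusted p = 0.000556, 0.000857, 0.0161, 0.017 and 0.0161), and none of them with an estimated correlation (adjusted p = 0.37, 0.555, 0.482, 0.37 and 0.555). The same filter left 2 of 11 T and NK cell, 7 of 10 monocyte and 1 of 3 neutrophil markers and ended those calls too (adjusted p = 0.241, 0.0903 and 0.262), with medians of 0.35, 0.32 and 0.63 against 0.67, 0.42 and 1.78 without it. Only 3 neutrophil markers could be tested, and their score was 2.10 in hypoxia mouse 5 and between -0.12 and 0.20 in the other hypoxia mice. All normoxia mice scored lower, between -0.92 and -0.25 (exact permutation p = 0.00794, adjusted p = 0.0794). Cholangiocyte, dendritic cell, erythroid, pancreas, and adipose and muscle markers were not called (camera adjusted p = 0.426, 0.221, 0.606, 0.179 and 0.225). Only 1 of the 14 pancreas markers could be tested (log2 fold change 0.41), so that result describes a single gene. The erythroid list, with 3 of 4 members below normoxia, had a median log2 fold change of -0.09. The adipose and muscle list, with 2 of 4 members above normoxia, had a median of -0.19. Its score per mouse was lower by 0.442 (exact permutation p = 0.0238, adjusted p = 0.115), and 2 members passed lower adjusted over the list alone. Hepatocyte markers were called slightly higher (median log2 fold change 0.08; camera adjusted p = 0.0323, and 0.527 with an estimated correlation), and Ahsg, the fetuin A gene, rose (edgeR adjusted p = 0.0493).

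**Figure D2:**
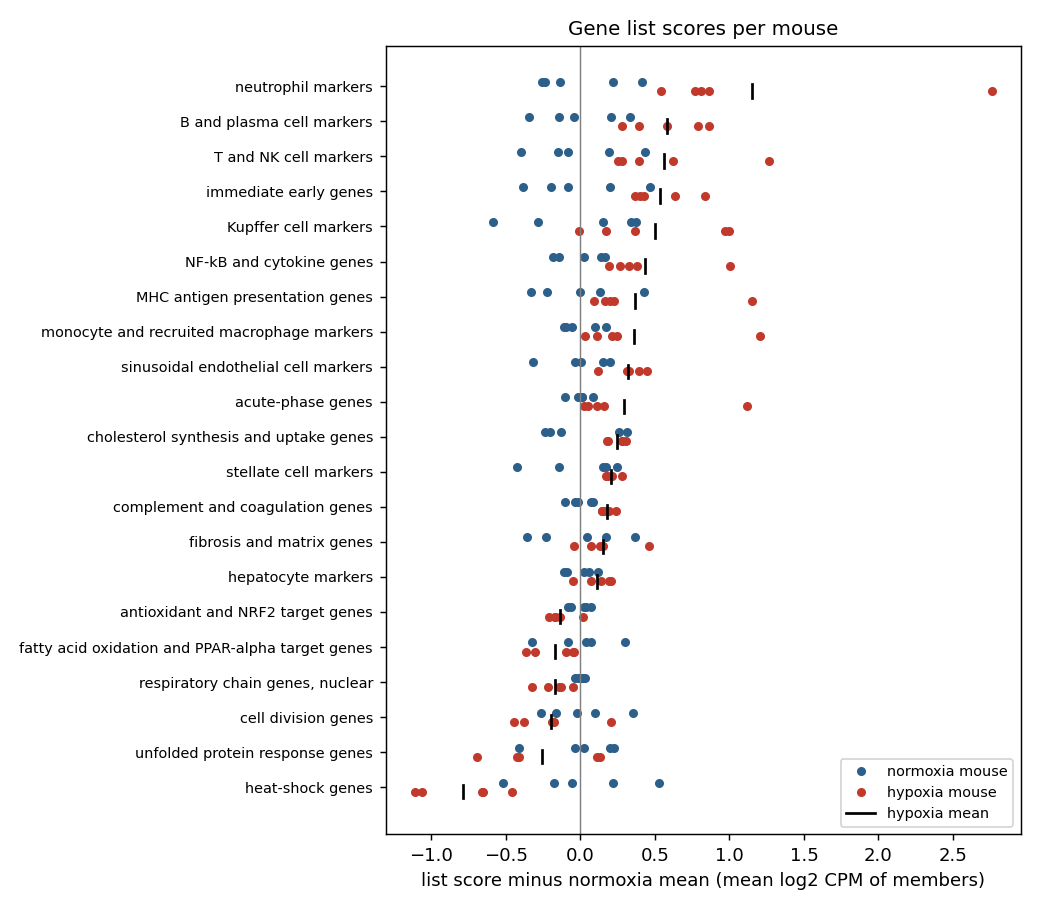
Mean log2 CPM of each list's members per mouse, minus the normoxia mean of that list (horizontal axis), for the 21 lists that camera called with a preset correlation; blue points are normoxia mice, red points hypoxia mice and the black line the hypoxia mean. In the neutrophil, acute-phase, MHC and monocyte lists 1 mouse, hypoxia mouse 5, lies far to the right of the other 4 hypoxia mice.

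In all, camera with the preset correlation called 21 of 40 lists, 15 higher and 6 lower. The others called were fibrosis and matrix genes (higher; adjusted p = 0.017, and 0.607 with an estimated correlation), antioxidant genes (lower; 0.0107 and 0.37), unfolded protein response genes (lower; 0.0154 and 0.555) and cell division genes (lower; 0.0391 and 0.555, and 0.136 with the filter of 1 CPM). With an estimated correlation 0 of the 40 lists passed (limma camera, 3 at an unadjusted p under 0.05). In the exact permutation test of scores per mouse 0 passed (16 at an unadjusted p under 0.05, smallest adjusted p = 0.0794). That smallest value belongs to the 4 lists whose groups did not overlap, each at the smallest possible p of 0.00794. They were the NF-kB and cytokine, complement and coagulation, and neutrophil lists (higher) and the respiratory chain list (lower). So few lists could not pass the adjustment over 40 whatever their difference, and the 0 is not evidence against a shift. Some calls with the preset correlation were lost when 1 mouse was left out: MHC (adjusted p = 0.188) and monocyte (0.198) without hypoxia mouse 5, stellate (0.227) without normoxia mouse 2, and fibrosis without hypoxia mouse 5 or normoxia mouse 2 or 3 (up to 0.299). So were unfolded protein response without hypoxia mouse 2 or normoxia mouse 3 (adjusted p up to 0.112), cell division without hypoxia mouse 3 or 4 or normoxia mouse 4 or 5 (up to 0.237), and hepatocyte markers without hypoxia mouse 1 or 2 or normoxia mouse 1 or 5 (up to 0.126). When the 10 mice were divided in other ways without regard to exposure, the preset correlation called a median of 11 lists, against 21 for the real groups. The HIF target list, which holds genes induced by low oxygen, was not called by camera (adjusted p = 0.426), with 11 of 29 members above normoxia. It passed fry's test for change in either direction (adjusted p = 0.0018), as did 17 of the 40 lists, this one included. Ndrg1, chosen after its values were seen, was the 1 member that passed adjusted over the list alone, at 46.6 ± 13.2 against 20.01 ± 6.31 CPM (edgeR adjusted p over all genes 0.0624). Vegfa stood at 257 ± 22.1 against 224 ± 25.9 CPM and Angptl4 at 64.7 ± 22.3 against 59.1 ± 14.5 CPM (SD, n = 5 each). Interferon-stimulated genes (adjusted p = 0.103), bile acid genes (0.543), iron genes (0.425), xenobiotic genes (0.91), glucocorticoid response genes (0.543), male-high (0.203) and female-high (0.835) genes, periportal (0.115) and pericentral (0.571) markers and gluconeogenic genes (0.774) were not called; for the last, camera pointed lower while the median log2 fold change was 0.08. The readouts Cyp7a1, the rate-limiting enzyme of bile acid synthesis, Hamp, the iron hormone hepcidin, and Col1a1 did not pass (edgeR adjusted p = 0.193, 0.766 and 0.913).

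**Figure D3:**
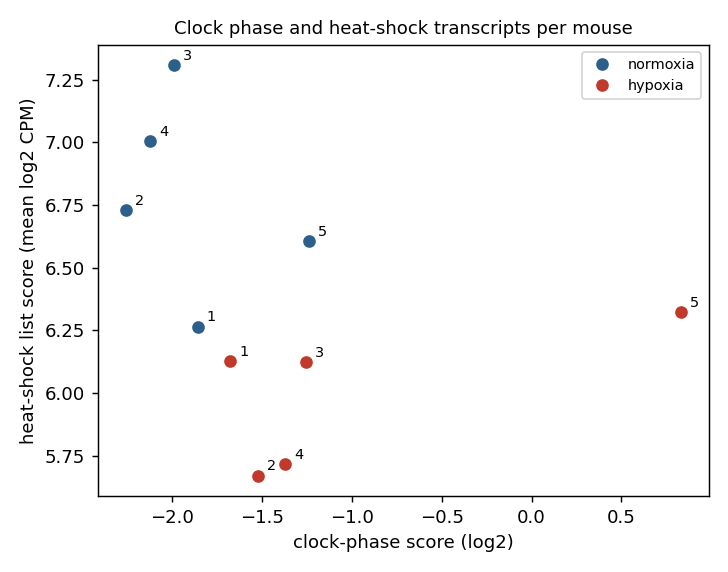
Heat-shock list score (mean log2 CPM of 16 genes, vertical axis) against the clock-phase score (mean log2 CPM of Nr1d1, Nr1d2, Dbp, Per3 and Tef minus that of Arntl, Npas2, Clock, Cry1 and Nfil3, horizontal axis) for each mouse, numbered within its group; normoxia is blue and hypoxia red. Hypoxia mouse 5 stands alone at a clock-phase score of 0.83, and the other 4 hypoxia mice lie between -1.68 and -1.26. Normoxia mouse 5 lies at -1.24, and the other normoxia mice lie between -2.26 and -1.86.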

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

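The tests that weigh the heat-shock and cell marker patterns were chosen after the results were seen; those on splits of the mice, GC content and transcript length were written before their results were seen. In 344 checks of single values within a group of 5, 17.2 would be flagged by chance and 25 were, 14 of them high values of hypoxia mouse 5. Those were, with the gap of that mouse to the next divided by the range of its group, S100a8 (0.878), Dbp (0.857), S100a9 (0.845), Saa1 (0.812), H2-DMb1 (0.806), S100a4 (0.732) and Tlr2 (0.711), the acute-phase (0.876), MHC (0.871), neutrophil (0.853), monocyte (0.814), dendritic cell (0.781) and NF-kB (0.766) list scores, and the share of reads in overlapping genes (0.748). Hypoxia mouse 1 stood high in Gck (0.819) and Ahsg (0.774) and low in Dlgap1 (0.884), and hypoxia mouse 2 stood low in Mogat1 (0.823). Normoxia mouse 1 stood high in Cidec (0.89) and low in Dnajb9 (0.822) and Herpud1 (0.789). Normoxia mouse 3 stood high in Per2 (0.711) and in the share of reads in overlapping genes (0.729), and low in Saa1 (0.795) and the dendritic cell score (0.779).

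For the number of called genes the splits argue against chance. Of 100 splits of the mice, out of 126 possible, only the real one gave as many as its 89 genes (1 of 100), and the highest other gave 9. For the number of called lists, 2 of 100 splits, the real one included, gave as many as its 21, so so high a count was uncommon among the splits drawn. The highest other also gave 21, with 4 hypoxia mice on one side, and the median of the others was 11. Since the preset correlation called that many lists without regard to exposure, the count does not show that any 1 list was shifted. Higher and lower calls differed in median transcript GC content (48.9% and 56.6%) and in median length (2830 and 2004 nt), with permutation p = 3.0e-05 and 0.013 over the calls. Over all tested genes the log2 fold change had a Spearman correlation of -0.072 with GC content and 0.171 with length. The slopes per library with GC content and length gave exact permutation p = 0.341 and 0.0873 between the groups. A correction of each library for its trend with GC content left the fold changes of the calls at a median ratio of 0.99 to the uncorrected ones. A correction for length left them at 0.969. For the called genes these ratios argue against either trend as the source, and 78 and 82 of the 89 calls remained past the threshold. The gene lists were not tested again after either correction, so a part of the length trend in their shifts stays open.

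Heat-shock transcripts and Per2 were lower together in intermittent hypoxia. The median over the heat-shock list was -0.44 or lower whichever mouse was left out, which argues against a single mouse. The clock-phase score was higher in hypoxia by 0.894 (exact permutation p = 0.0476, n = 5 each), in line with a later circadian time in those livers, but without hypoxia mouse 5 the difference was 0.437 (exact permutation p = 0.0873). With that score as a covariate the median over the heat-shock genes and Per2 was -0.70 (without it -0.56), so linear adjustment for the score did not reduce the decrease. This fit cannot decide whether circadian time accounts for the decrease. It leans on hypoxia mouse 5, whose score of 0.83 stands apart from those of the other mice (-2.26 to -1.24). The overlap of the groups came from normoxia mouse 5, whose score of -1.24 lay above those of hypoxia mice 1 to 4 (-1.68 to -1.26). The other normoxia mice lay below these hypoxia mice (-2.26 to -1.86). Of the 3 genes called without the covariate, Per2 stayed past the threshold. Hspa1a (-2.80 ± 0.68, edgeR adjusted p = 0.0728, against -2.75 ± 0.51) and Hspa1b (-2.92 ± 0.61, edgeR adjusted p = 0.0665, against -2.62 ± 0.47) did not, because their standard errors grew. Whether the livers were taken at the same hour in both groups is not in the labels, and an effect of hypoxia, of harvest hour or of body temperature on these genes stays open.

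Endothelial, Kupffer, B and T cell marker lists were called higher in intermittent hypoxia with the preset correlation and not with an estimated one (camera adjusted p = 0.37, 0.555, 0.37 and 0.37), no marker of theirs passed over all genes, the dendritic cell list was not called (0.221), and the B and T calls rest on scarce transcripts, since with a filter of 1 CPM, which left 2 members of each, they were lost (0.487 and 0.241). The median rise of the endothelial, Kupffer, B and T lists was 0.381 or more whichever mouse was left out (0.532 with all), which argues against a single mouse, although without hypoxia mouse 5 the Kupffer and T lists gave exact permutation p = 0.222 and 0.0794. A lower share of hepatocytes in the tissue pieces would raise all non-hepatocyte lists alike and cannot be told apart from a change in those cells: over 15 pairs of 6 such lists the smallest p adjusted by the largest t of each assignment of the mice was 0.159 (exact permutation, n = 5 each), for the B list, which rose more than the cholangiocyte list by 0.476 (unadjusted exact permutation p = 0.00794), and this does not show that the lists rose alike. The criterion was changed 2 times after values had been seen: an earlier wording took hepatocyte markers that did not fall (their score was higher by 0.112, exact permutation p = 0.111), or any pair with an unadjusted p under 0.05 (2 of 15 pairs), as excluding this explanation, and by that wording it would have been excluded. That wording was dropped because abundant hepatocyte transcripts would hide a small loss and because 15 pairs were compared, and a Benjamini-Hochberg adjustment (smallest adjusted p = 0.119) was then replaced because a single pair could not pass it in this design.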

How the results depend on the processing

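The corrections for GC content and length and the clock-phase covariate were chosen after seeing the data. All 32 called genes named by rule kept their direction in every fit that tested them, up to 24 each; Ugcg, Aatk, Olig1, Plin5 and Agpat2 alone also stayed past the threshold in all. The count of 89 calls (40 higher, 49 lower) became 662 (285 and 377) with DESeq2, 241 (120 and 121) with voom and quality weights and 589 (245 and 344) with 1 surrogate variable, and each of these held all 89; the cause was not tested. It was 395 (187 and 208) at an adjusted threshold of 0.1, 0 (0 and 0; 2427 at an unadjusted p under 0.05, edgeR) at 0.01 and 13 (5 and 8) with an absolute log2 fold change of at least 1, by construction. Scaling by library size alone gave 69 calls (17 higher and 52 lower). The balance of direction turned in other settings. Higher calls outnumbered lower ones with upper-quartile scaling (49 and 41), the GC correction (60 and 51), the length correction (67 and 55) and a filter at a mean of 50 counts (60 and 53). With 1 mouse left out the count ranged from 12 (without hypoxia mouse 2) to 236 (without hypoxia mouse 1), from 3 to 115 higher and from 9 to 121 lower; fewer mice lower the power, but the cause of the larger counts without hypoxia mouse 1 (236) or 5 (204) was not tested. The 21 called lists became 0 with an estimated correlation, 3 with fry and 16 with the filter of at least 1 CPM in 5 libraries, where the cell division, monocyte, neutrophil, T and NK cell, and B and plasma cell lists lost their call (adjusted p = 0.136, 0.0903, 0.262, 0.241 and 0.487) with 14 of 19, 7 of 10, 1 of 3, 2 of 11 and 2 of 10 members left. On ranks 20 were called, and the hepatocyte list was not (adjusted p = 0.0644). They ranged from 19 to 24 with 1 mouse left out, but not with the same lists: the MHC, monocyte, stellate, fibrosis, unfolded protein response, cell division and hepatocyte lists each lost their call without at least 1 mouse (highest adjusted p = 0.188, 0.198, 0.227, 0.299, 0.112, 0.237 and 0.126). The interferon, dendritic cell, periportal, male-high and triglyceride synthesis lists each gained one (lowest adjusted p = 0.0038, 0.00572, 0.0307, 0.0487 and 0.0418). The measures of library composition past the threshold were 0 with all mice and ranged from 0 to 2, the highest without hypoxia mouse 5. In that test 1 measure alone could not pass. No list score passed under any alternative, but in that test a few lists alone could not pass even at the smallest possible p.

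Reversals of direction were limited to genes and lists that did not pass. With the clock covariate the log2 fold changes were -0.84 for Saa1, -0.31 for Ccl2, 0.079 for Arntl, -0.88 for Dbp and 0.17 for Per1; with voom they were -0.016 for Ccl2, -0.075 for Dbp and 0.049 for Per1, and with the GC correction 0.053 for Per1. Xenobiotic metabolism genes reversed with a filter of 1 CPM (median -0.00565, where the test alone changed direction). Ranges with 1 mouse left out were -0.0091 to 0.29 for Angptl4, -0.28 to 1.51 for Saa1, -0.077 to 0.79 for Ccl2, -0.52 to 0.10 for Col1a1, -0.0055 to 0.17 for Scd1, -0.033 to 0.11 for Cpt1a, -0.46 to 0.82 for Dbp, -0.30 to 0.18 for Per1, -0.035 to 0.32 for interferon-stimulated genes, -0.019 to 0.12 for bile acid synthesis and transport genes, -0.059 to 0.022 for xenobiotic metabolism genes, -0.044 to 0.18 for gluconeogenesis and insulin response genes, -0.13 to 0.12 for female-high genes and -0.061 to 0.022 for pericentral hepatocyte markers. For lists these are medians, and the reversed direction is that of camera. Counts near the floor (Tnf, Epo, Hspa1a in hypoxia) limit what can be said of those genes.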

Other observations

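The genes of these paragraphs outside the naming rule were chosen after their values were seen. They were picked one by one and make no tested group; the steatohepatitis list, which holds Cidea, Plin4, Cd36 and Plin2, was not called (camera adjusted p = 0.195), with 10 members above and 11 below normoxia. Cidea averaged 0.28 ± 0.107 CPM in hypoxia and 3.87 ± 6.00 CPM in normoxia (SD, n = 5 each), Plin4 5.96 ± 2.05 against 15.3 ± 6.72 CPM, Cd36, a fatty acid transporter, 96.7 ± 23.4 against 175 ± 70.4 CPM, Pparg 9.03 ± 1.95 against 13.7 ± 4.57 CPM and Cfd, known from fat cells, 1.24 ± 0.838 against 6.72 ± 4.25 CPM. None of these 5 passed over all genes (edgeR adjusted p = 0.114, 0.0841, 0.144, 0.165 and 0.0753). Normoxia mouse 1 held the highest Cidea, at 14.6 CPM. Plin2, the most abundant droplet coat gene of liver, was 804 ± 52.0 against 878 ± 125 CPM (adjusted p = 0.507).

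Gck averaged 227 ± 77.7 against 385 ± 81.7 CPM (SD, n = 5 each), Thrsp 309 ± 80.5 against 538 ± 174 CPM and Srebf1 170 ± 41.0 against 248 ± 45.9 CPM, while Igfbp1 averaged 81.9 ± 26.4 against 39.5 ± 26.8 CPM. Their edgeR adjusted p over all genes were 0.114, 0.115, 0.139 and 0.237. The gluconeogenesis and insulin response list, which holds Gck and Igfbp1, was not called (camera adjusted p = 0.774), with 12 members above and 9 below normoxia, and neither was the list of fatty acid and triglyceride synthesis genes, which holds Gck, Thrsp, Srebf1 and Fasn (0.221), with 13 above and 11 below. Fasn averaged 1624 ± 173 against 1960 ± 817 CPM (adjusted p = 0.577). Cirbp, a cold-inducible RNA-binding protein gene, averaged 23.2 ± 3.21 against 17.1 ± 2.58 CPM (adjusted p = 0.0997), and Rbm3, of the same class, 32.4 ± 4.42 against 34.9 ± 6.42 CPM (adjusted p = 0.699).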
